A study of Mus musculus with 24 samples.

How the data were processed

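RNA of haematopoietic stem cells (HSC), myeloid progenitors (MP) and B cell progenitors, sorted from bone marrow of 129ola mice with reduced (hypomorph) or wildtype Dnmt1, was hybridised to Affymetrix expression arrays. Per the labels, total RNA of 35000 to 100000 sorted cells was extracted with a Qiagen micro kit, biotinylated cRNA was prepared with the small sample protocol of the manufacturer, and the authors computed RMA values. The deposited values are read as log2 intensities because RMA gives that unit and they run from 1.93 to 14.99; the base of the logarithm is inferred from the values, and every fold change here rests on that reading. The version of RMA is not given in the sources used here.

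The value table has 45101 probe sets and 24 columns. Of these columns, 13 hold a normalization of all arrays and 11 a further normalization of the HSC and MP arrays. Columns with the same label correlated at 0.999 between the normalizations, and at most at 0.995 with any other label, so they were treated as the same arrays and never counted as further replicates. The normalization of 13 arrays was used throughout and the other served as an alternative. Group sizes were 3 (HSC hypomorph), 2 (HSC wildtype), 3 (MP hypomorph), 3 (MP wildtype) and 2 (B progenitor wildtype), and 0 columns were left unused. No detection calls were used, so whether a dim gene lay above background is not known.

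Of the probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none, and only those with 1 symbol were used. Current symbols were looked up by Entrez identifier for 34754, and 0 changed. A probe set was kept when at least 2 arrays reached 4.64, the median of all values. The filter counted arrays of both genotypes, so a gene low in wildtype cells could pass through hypomorph arrays alone. The probe set with the highest mean stood for its gene. This left 12745 of 18194 genes, 7547 of them with more than 1 probe set. Of the 1375 genes called in HSC, 675 had several tested probe sets, with a further probe set of the other sign in 180 and a called one of the other sign in 2; in MP these numbers were 25 of 75, 6 and 0.

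A single limma model of the 5 groups, with 8 residual degrees of freedom, gave moderated t tests for 7 comparisons: hypomorph against wildtype in HSC and in MP, the difference of these effects, MP against HSC in each genotype, and B progenitors against HSC and MP in the wildtype. P-values were adjusted by Benjamini and Hochberg in each comparison, and genes under 0.05 are called. Group values are means with SD, and SE are those of limma. Fixed lists of 18 kinds of genes, written before the values were seen, were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation, with adjustment over the 18 lists. Calls adjusted over the list alone use the members as the only genes. A further pair of lists took the 100 genes with the highest and the lowest ratio of wildtype MP to B progenitors. The overlap of calls was tested with Fisher's exact test. For the covariance of comparisons that share the wildtype HSC arrays, 100 simulations without any effect were made from the residual spread of each gene, and the covariance was repeated with 1 wildtype HSC array on each side.

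Genes were named by a rule written beforehand. In both genotype comparisons it names Dnmt1, Gata1, Id2 and Cebpa, the 6 largest called rises and 6 largest called falls with all arrays of a group on the same side of the other group, and up to 2 called members of each list with the largest change, or the member with the smallest p where none was called. In the comparisons of cell types it names the 4 highest, the 4 lowest and up to 2 called members of the erythroid, granulocyte-monocyte progenitor, B lineage and stem cell lists, and for the difference of effects up to 5 genes in each direction.

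The calling was tested on simulated data, with 200 changed genes in each of 10 runs. In the HSC comparison 0.746%, 31.3% and 86.1% of genes changed by a log2 fold of 0.5, 1 and 2 were recovered, and 4.60% of calls were false. In the MP comparison 2.09%, 42.5% and 91.4% were recovered, and 5.01% of calls were false. Of 180 simulated lists without a change, 5 in HSC and 0 in MP passed an unadjusted p of 0.05 in camera. All groups were given the same spread for a gene. The shares of recovered and false calls therefore do not test a spread that differs between groups. The noise of each gene was drawn on its own, so the members of these lists were not correlated. The estimated correlation was 0.204 in the neutrophil list and 0.186 in the replication list, so the simulation does not test the preset of 0.01.

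The alternatives tried were the other normalization, the replicate number as a block, only the arrays compared, a trended or robust prior, array weights, no filter, a filter at the 75th percentile (7.10), the mean of all probe sets of a gene, every probe set, centring on the median, a minimum fold change, the estimated correlation, the fry test, lists of 50 or 200 genes, and leaving out each array in turn. Added after seeing the data were array weights computed gene by gene, the replication list left out of the genes tested, the fry test with arrays centred, and further settings for the overlap, the covariance and the list of myeloid genes. With the replication list left out, 1323 genes were called in HSC and 75 in MP. R 4.3.3 with limma 3.58.1 was used for the statistics, and Python 3.11.15 with matplotlib 3.10.9 for the figures.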

Results

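Transcript levels were measured with Affymetrix expression arrays of 45101 probe sets in cell populations sorted from the bone marrow of 129ola mice aged 8 to 12 weeks. Dnmt1 encodes the maintenance DNA methyltransferase, which copies methylation marks to the new strand after replication. Mice carrying the Dnmt1-/chip genotype, in which a null allele is combined with an allele of reduced function, are called hypomorphs, and Dnmt1+/+ mice are the wildtype. The data comprised 3 arrays of hypomorph and 2 of wildtype haematopoietic stem cells (HSC), 3 arrays of hypomorph and 3 of wildtype myeloid progenitors (MP), and 2 arrays of wildtype B cell progenitors. The values are log2 intensities, with array medians between 4.56 and 4.74 over all probe sets. The number of arrays limits the precision of every value below. The labels do not state that the arrays of a group came from separate animals, so the p-values measure only the spread between these arrays. In wildtype HSC, MP and B progenitors and in hypomorph MP, the Y-linked gene Eif2s3y was low on some arrays and high on others. Within those groups the arrays therefore do not all repeat a single RNA source, and how far the spread is technical is not known. Of the genes represented, 12745 passed the intensity filter and were tested.

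Dnmt1 itself was lower in hypomorph cells of both types. In HSC its level was 11.69 ± 0.15 (SD, n = 2) in wildtype and 8.94 ± 0.42 (SD, n = 3) in hypomorph arrays, a log2 fold change of -2.75 (SE 0.24), or 6.75-fold lower, with a limma adjusted p of 2.83e-05. In MP the level was 11.48 ± 0.22 (SD, n = 3) in wildtype and 8.14 ± 0.12 (SD, n = 3) in hypomorph arrays, a log2 fold change of -3.34 (SE 0.22), or 10.1-fold lower, with a limma adjusted p of 7.23e-06. Wildtype B progenitors had a level of 12.32 ± 0.12 (SD, n = 2). The 3 probe sets of Dnmt1 differed in size of effect. A further probe set gave log2 fold changes of -2.51 in HSC and -3.15 in MP, and another gave -0.75 in HSC (limma adjusted p = 0.110, over all probe sets) and -1.67 in MP (limma adjusted p = 0.00802).

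**Figure D1:**
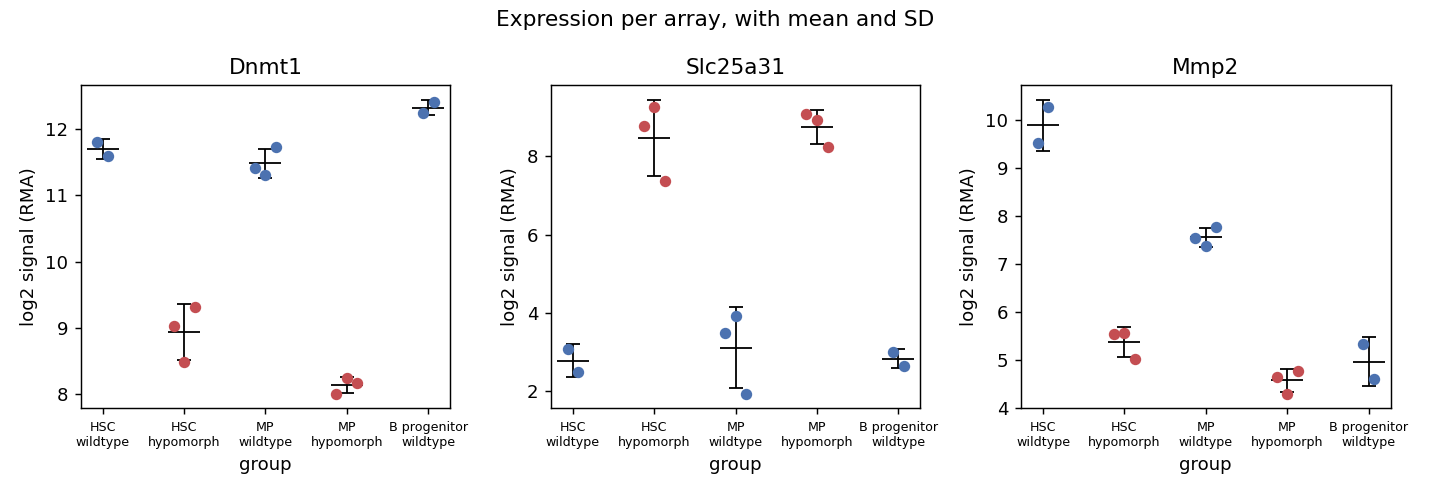
Log2 expression of Dnmt1, Slc25a31 and Mmp2 on each of the 13 arrays, by group, where each point is an array and the bar is the group mean. Dnmt1 and Mmp2 lay lower, and Slc25a31 higher, on every hypomorph array than on any wildtype array of the same cell type.

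The first comparison asked how reduced Dnmt1 affects expression in stem cells, and in particular the genes of the myeloid and erythroid lineages that the series title names. Some of the genes that mark granulocyte, mast cell and erythroid precursors rose in hypomorph HSC. The neutrophil granule protease gene Ctsg rose by a log2 fold change of 3.42 (SE 0.39), from 7.19 ± 1.26 (SD, n = 2) to 10.61 ± 0.32 (SD, n = 3), the mast cell carboxypeptidase gene Cpa3 rose by 3.34 (SE 0.30), and Rhag, a component of the erythrocyte Rh complex, rose by 2.63 (SE 0.41). Most of the DNA replication genes tested rose, and some of the genes that mark stem cells fell, among them Ndn by -2.63 (SE 0.23). The largest rise was that of Slc25a31, which encodes an ADP/ATP carrier of the germ line, at 5.70 (SE 0.56), and the largest fall that of the matrix metalloproteinase gene Mmp2, at -4.52 (SE 0.29). Of the 12745 genes tested, 1375 passed a limma adjusted p of 0.05, 685 higher and 690 lower in hypomorph HSC, and 1008 of them changed by at least 2-fold. The median over all genes was shifted by -0.11, and centring each array on its median gave 864 higher and 566 lower, or 60.4% higher against 49.8% without centring. The camera tests below compare each list with all other genes and so are relative to that shift, and the fry tests of limma, which set a list against no change, are not.

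Apart from Slc25a31, the genes with the largest rises in hypomorph HSC were Ccr1, a chemokine receptor of myeloid cells (4.99, limma adjusted p = 5.86e-07), Chdh, the choline dehydrogenase of mitochondria (4.22), Gem, a small GTPase (4.09), the butyrophilin-like gene Btnl9 (3.95) and Depdc1a (3.89, limma adjusted p = 5.02e-04). Apart from Mmp2, Dnmt1 and Ndn, the largest falls were those of Ndnf (-3.12, limma adjusted p = 0.00874), the cyclic nucleotide phosphodiesterase gene Pde2a (-2.82) and the inhibin subunit gene Inha (-2.61). Ndnf was -1.45 without HSC wildtype 1 and -4.78 without HSC wildtype 2, still called. Among the transcription factors named beforehand, Gata1, which drives erythroid and megakaryocyte differentiation, rose by 1.33 (SE 0.31, limma adjusted p = 0.0155), and the helix-loop-helix inhibitor Id2 rose by 1.75 (SE 0.33, limma adjusted p = 0.00528). Cebpa, which drives granulocyte differentiation, had a log2 fold change of 0.89 (SE 0.29, limma adjusted p = 0.0693). Cebpa passed the threshold without HSC wildtype 2 (1.37, adjusted p = 0.0301), with arrays centred (0.96) and in the second normalization (1.08). The call of Gata1 was lost without HSC wildtype 2 (1.16, adjusted p = 0.149), and the call of Id2 was lost when its probe sets were averaged (0.58), with a value of 1.14 under array weights. Averaging the probe sets of a gene also moved Ccr1 to 3.33, Btnl9 to 2.03 and Ndn to -1.40, with their calls kept.

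Of the 35 measured genes of the granulocyte-monocyte progenitor list, 10 rose in hypomorph HSC and 0 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.39. Besides Ctsg these included Ms4a3, a marker of granulocyte-monocyte progenitors (3.27, SE 0.42). Other members of the list, the granule protease genes Elane and Prtn3, had values of -0.12 (SE 0.49) and -0.20 (SE 0.21), and are named after their values were seen. The list was higher as a set (camera adjusted p = 3.60e-05; adjusted p = 0.169 with an estimated correlation). Of 15 measured mast cell, basophil and eosinophil genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.93, and the mast cell chymase gene Cma1 rose by 3.25 (camera adjusted p = 2.19e-05; adjusted p = 0.0640 with an estimated correlation). Of 34 erythroid genes, 3 rose, Rhag, Gata1 and the transferrin receptor gene Tfrc (1.24), and the biliverdin reductase gene Blvrb fell by 0.99, with the same counts adjusted over the list alone. Tfrc and Blvrb are named after their values were seen. The erythroid median was 0.15 (camera adjusted p = 0.0186; adjusted p = 0.188 with an estimated correlation). Without HSC wildtype 2 the erythroid median was -0.02 and the camera call was lost (adjusted p = 0.0968), as it was at the 75th percentile filter (median 0.10, adjusted p = 0.205) and in the fry test of limma (0.0681, or 0.1305 with arrays centred). Of 22 genes of mature neutrophils and monocytes, 1 rose, the chemokine gene Ccl9 (1.39), and 0 fell, also adjusted over the list alone (median 0.47, camera adjusted p = 0.0186; adjusted p = 0.380 with an estimated correlation). That camera call was lost without HSC hypomorph 1 or HSC wildtype 2 (adjusted p from 0.106 to 0.1303), at the 75th percentile filter (0.09005) and in fry (0.110, or 0.0794 with arrays centred). Without HSC hypomorph 1 the median of the neutrophil list was 0.10, of the mast cell list 0.55 and of the erythroid list 0.09. The neutrophil median was 0.28 and 0.29 without HSC wildtype 1 and 2, the erythroid median 0.24 and 0.23 without HSC hypomorph 2 and HSC wildtype 1, and the granulocyte-monocyte progenitor median 0.12 without HSC wildtype 2. None of 21 megakaryocyte genes rose and 3 fell (2 and 3 adjusted over the list alone), among them the platelet basic protein gene Ppbp (-1.86) and the thromboxane synthase gene Tbxas1 (-1.47), and the list was not shifted (camera adjusted p = 0.968). The call of Ppbp was lost without HSC wildtype 1 (-1.07, adjusted p = 0.107), and that of Tbxas1 without any of 10 of the arrays left out in turn (adjusted p from 0.05003 to 0.385), the largest value being without HSC wildtype 2 (-0.95). The limma call of Tbxas1 was also lost in the second normalization (0.0554) and without a filter (0.0561).

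Lists of lymphoid genes were not called by camera in hypomorph HSC, and the fry test of limma called the B lineage list lower (adjusted p = 0.0302), but not with arrays centred (0.848). Of 35 B lineage genes, 1 rose and 2 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.490). Btla, an inhibitory receptor of lymphocytes, rose by 2.56, and the B cell receptor subunit gene Cd79b fell by 0.89. Of 28 lymphoid priming genes, 1 rose, Cd48 (1.61), and 4 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.431), with the lymphotoxin gene Ltb falling most, by 2.23. Of 17 T and NK cell genes, 3 rose and 1 fell, also adjusted over the list alone (median -0.07, mean 0.20, camera adjusted p = 0.490). The members that rose most were Gzmb (2.27), a granule protease gene that mast cells also express, and Nkg7 (1.88), which is also in the granulocyte-monocyte progenitor list. Of 15 macrophage and stroma genes, 0 rose and 1 fell, the collagen gene Col1a2 (-1.35), also adjusted over the list alone (camera adjusted p = 0.932). Without HSC wildtype 2 the calls of Cd48 (adjusted p = 0.0755), Gzmb (0.0785) and Col1a2 (-0.72, adjusted p = 0.313) were lost. The limma call of Cd79b was lost without any of 7 arrays left out in turn (adjusted p from 0.0505 to 0.170), among them all HSC arrays but HSC hypomorph 1, and in the second normalization (0.0871). Array weights ended the calls of Gzmb (1.34, adjusted p = 0.0599) and Cd79b (0.0617), and averaged probe sets that of Col1a2 (-0.85, adjusted p = 0.0704).

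The DNA replication and mitosis list had the largest median rise of the called lists in hypomorph HSC, except at the 75th percentile filter, where the mast cell, basophil and eosinophil list had a median of 2.27. Of its 48 measured genes, 35 rose and 0 fell (40 and 1 adjusted over the list alone), with a median log2 fold change of 1.21 (camera adjusted p = 1.01e-30; adjusted p = 0.0159 with an estimated correlation). The cyclin gene Ccne2 rose by 3.76 (SE 0.33) and the spindle checkpoint kinase gene Bub1 by 2.74 (SE 0.35). The mean level of the list was 8.35 ± 0.02 (SD, n = 2) in wildtype HSC, 9.62 ± 0.15 (SD, n = 3) in hypomorph HSC and 9.81 ± 0.07 (SD, n = 3) in wildtype MP. Of 25 p53 targets and cell cycle inhibitors, 4 rose and 0 fell, also adjusted over the list alone (median 0.13, camera adjusted p = 0.0186; adjusted p = 0.188 with an estimated correlation). Among these were the apoptosis effector gene Perp (1.76) and the inhibitor gene Cdkn1b (1.63). Of 22 genes of the DNA methylation machinery other than Dnmt1, 4 rose and 0 fell, also adjusted over the list alone (median 0.14, camera adjusted p = 0.0186; adjusted p = 0.169 with an estimated correlation). Uhrf1, which recruits Dnmt1 to replicating DNA and is also in the replication list, rose by 2.29, and Zbtb38, which encodes a methyl-CpG binding protein, rose by 2.93. The p53 list was not called in the fry test of limma (adjusted p = 0.0604), and was with arrays centred (median 0.20, adjusted p = 0.00224). Without HSC wildtype 2 the p53 list (median 0.01, adjusted p = 0.0675) and Cdkn1b (1.49, adjusted p = 0.0647) were no longer called. Zbtb38 was not called without HSC wildtype 2 (1.74) or HSC hypomorph 2 (2.71), with adjusted p from 0.0553 to 0.234, nor with probe sets averaged (0.86), which also moved Cdkn1b to 1.01. Uhrf1 was 1.48 without HSC wildtype 2, still called. The p53 median was 0.03, 0.04 and 0.25 without HSC hypomorph 1, 2 and 3, and that of the DNA methylation machinery 0.07 without HSC hypomorph 3 and -0.00171 without HSC wildtype 1. The latter was also 0.07 in the second normalization, 0.09 with probe sets averaged, 0.22 with arrays centred and 0.23 at the 75th percentile filter.

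Of 45 measured stem cell genes, 11 fell and 1 rose in hypomorph HSC (14 and 2 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 3.98e-04; adjusted p = 0.183 with an estimated correlation). Ndn and Ltb fell most in this list, whose median was -0.39 without HSC hypomorph 3. Of 30 imprinted genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 1.71e-04; adjusted p = 0.0159 with an estimated correlation), and the maternally expressed noncoding gene Meg3 fell by 2.56 and Ndn by 2.63. Of 24 germline and pluripotency genes, 5 rose and 3 fell, also adjusted over the list alone (median 0.21, camera adjusted p = 0.0196; adjusted p = 0.169 with an estimated correlation). Beside Slc25a31, the germ cell helicase gene Ddx4 rose by 2.70 (SE 0.32). The call of this list was lost without HSC hypomorph 3 (adjusted p = 0.0554) and without HSC wildtype 1 (adjusted p = 0.158), and at the 75th percentile filter the germline median was -0.01 (adjusted p = 0.587). It was 0.35 without either wildtype HSC array and 0.38 with probe sets averaged. Of 39 interferon response genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 7.06e-04; adjusted p = 0.183 with an estimated correlation), and Ifit1 fell by 1.93 and Rsad2 by 1.49. Of 29 immediate early and heat shock genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.0284; adjusted p = 0.188 with an estimated correlation), among them Junb (-1.30) and Egr1 (-1.22). The call of the immediate early list was lost without HSC hypomorph 1, HSC hypomorph 2 or HSC wildtype 2 (adjusted p from 0.0552 to 0.135), with probe sets averaged (0.06995) and in fry with arrays centred (0.0533), and its median was -0.30 without HSC hypomorph 1 or HSC wildtype 2 and -0.75 without HSC wildtype 1. Lost too were the limma calls of Junb (-0.77, adjusted p = 0.1403) and Egr1 (-0.84, adjusted p = 0.171) without HSC wildtype 2. Averaged probe sets moved Meg3 to -1.10 and Rsad2 to -0.88, with their calls kept. The imprinted list was also lower in wildtype MP than in wildtype HSC, with 11 of 30 genes lower and 1 higher. Its median there was -0.40 (camera adjusted p = 0.00204, or 0.0239 with an estimated correlation), so a fall of this list was not particular to the hypomorph. The imprinted and stem cell lists share 2 members. None of the 4 sex-linked genes was called, also adjusted over the list alone (camera adjusted p = 0.490), and Eif2s3y had a log2 fold change of 2.61 (SE 2.51, limma adjusted p = 0.553). The wildtype HSC arrays differed widely in these genes, so the absence of a call does not show that sex was balanced.

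The number of genes called in HSC depended on the arrays in the fit. It was 453, 253 of them higher, without HSC wildtype 2, 688, 359 of them higher, without HSC hypomorph 2, and 139, 82 of them higher, when the fit held only the 5 HSC arrays instead of all 13. The 75th percentile filter gave 652 higher and 486 lower, so the even split of higher and lower genes depended on the setting. With only the arrays compared, the count in HSC (139) was below that in MP (164). The larger count in HSC than in MP thus rests on the spread shared by all groups.

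**Figure D2:**
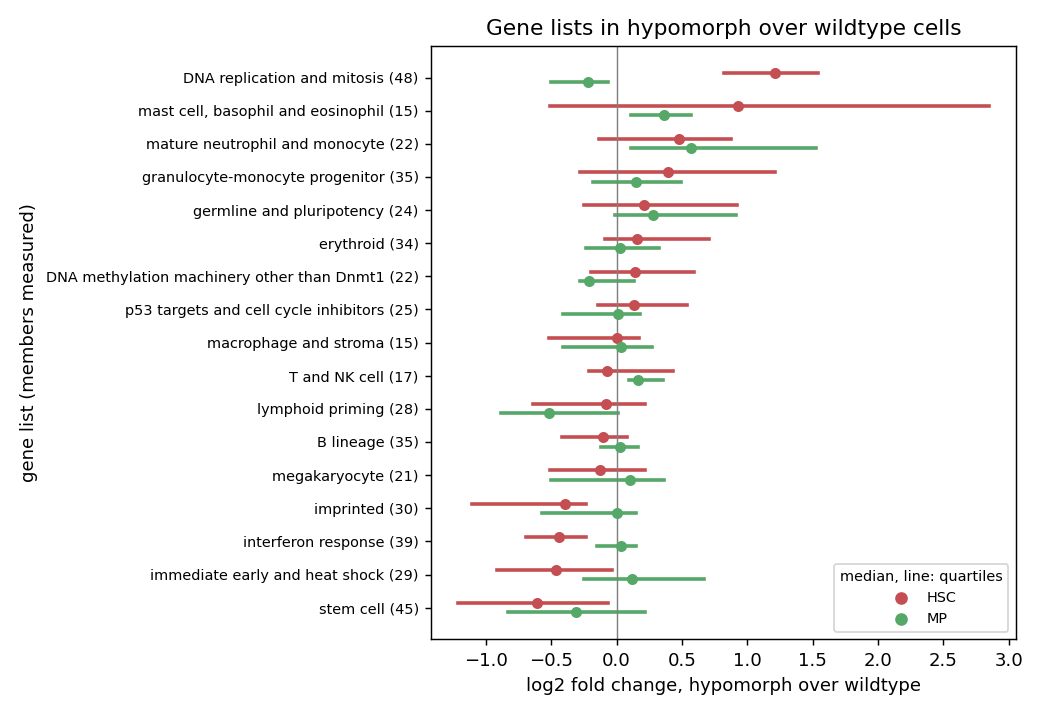
Median log2 fold change, hypomorph over wildtype, of 17 gene lists in HSC (red) and MP (green), with horizontal lines from the lower to the upper quartile of the members. The DNA replication and mitosis list has a median of 1.21 in HSC and -0.22 in MP.

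A separate measure of lineage used lists that rest on no HSC array. The 100 genes with the highest ratio of wildtype MP to wildtype B progenitors had a median log2 fold change of 0.24 and a mean of 0.63 in hypomorph HSC, with 24 higher and 4 lower (camera p = 1.11e-08; p = 0.00514 with an estimated correlation). The mean level of these genes was 7.95 ± 0.01 (SD, n = 2) on the wildtype and 8.57 ± 0.14 (SD, n = 3) on the hypomorph HSC arrays. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 2 arrays allow. The 100 genes with the lowest ratio had a median of -0.21, with 5 higher and 8 lower (camera p = 0.1004, or p = 0.132 with an estimated correlation). Among them are Jchain and Igha, which mark antibody-secreting cells. Leaving out 1 array at a time put the median of the first list between 0.14 (without HSC hypomorph 1) and 0.39 (without HSC hypomorph 3). The second list passed the threshold without HSC hypomorph 3 (-0.24), without HSC wildtype 2 (-0.21) and at the 75th percentile filter, a setting chosen after seeing the data. The median of the first list was 0.41 with 50 genes and 0.06 with 200 genes in place of 100.

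The same genotypes were compared in myeloid progenitors. In hypomorph MP, Slc25a31 rose by 5.65 (SE 0.50), from 3.10 ± 1.04 (SD, n = 3) to 8.75 ± 0.45 (SD, n = 3), and Syce1, a component of the synaptonemal complex of meiotic chromosomes, rose by 2.51 (SE 0.40). Dntt, which encodes the terminal deoxynucleotidyl transferase of lymphoid precursors, fell by 4.18 (SE 0.29), from 10.22 ± 0.41 (SD, n = 3) to 6.04 ± 0.23 (SD, n = 3). The heat shock gene Hspa1b fell by 4.91 (SE 0.86), the chromatin protein gene Hmga2 by 3.33 (SE 0.27), Mmp2 by 2.99 (SE 0.26) and the syndecan gene Sdc1 by 2.61 (SE 0.29). The other large rises were those of the small heat shock protein gene Cryab (2.98), Wfdc21 (2.74), Cma1 (2.57) and the muscle creatine kinase gene Ckm (2.52). Of the 12745 genes tested, 75 passed a limma adjusted p of 0.05, 43 higher and 32 lower, and 71 of these changed by at least 2-fold. At an unadjusted p of 0.05, 1911 genes passed. Gata1 (-0.27, limma adjusted p = 0.668), Id2 (1.10, 0.148) and Cebpa (0.40, 0.487) were not called. With probe sets averaged, Sdc1 was -0.85 (limma adjusted p = 0.0430), Cryab 1.54 and Ckm 1.35, still called, and Id2 0.55.

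The gene lists called by camera in hypomorph MP were those of the germ line, of neutrophils, of lymphoid priming, of T and NK cells, and of DNA replication and mitosis. Of 24 germline and pluripotency genes, 4 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 5.46e-06; adjusted p = 0.0395 with an estimated correlation). Of 22 genes of mature neutrophils and monocytes, 2 rose, Wfdc21 and the peptidylarginine deiminase gene Padi4 (1.44), and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 2.43e-07; adjusted p = 0.158 with an estimated correlation). Of 28 lymphoid priming genes, 3 fell, Dntt, the cytokine receptor gene Flt3 (-1.46) and the interleukin receptor gene Il7r (-1.31), and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 1.22e-04; adjusted p = 0.158 with an estimated correlation). Il7r is named after its value was seen. The T and NK cell list was higher, with 1 of 17 genes risen, Thy1 (1.22), and 0 fallen (2 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.0145; adjusted p = 0.292 with an estimated correlation). The DNA replication and mitosis list was lower as a set, with 0 of 48 genes called in limma, also adjusted over the list alone (median -0.22, camera adjusted p = 0.00904; adjusted p = 0.564 with an estimated correlation). Its member with the smallest p, Nusap1, had a value of -1.01 (limma adjusted p = 0.197), and ran from -1.05 to -0.27 in the settings other than leaving out an array. The replication call was lost without MP hypomorph 2 (adjusted p = 0.0596) and in the fry test (0.215, or 0.0765 with arrays centred). The camera call of T and NK cell genes was lost without MP hypomorph 2 or MP wildtype 3 (adjusted p from 0.0560 to 0.0596) and in fry with arrays centred (0.0765). At the 75th percentile filter the median was 1.07 for the germline list, 1.46 for the neutrophil list and 0.42 for the T and NK cell list. With probe sets averaged it was -0.17 for the lymphoid priming list, and with arrays centred 0.28 for the T and NK cell list and -0.11 for the replication list.

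**Figure D3:**
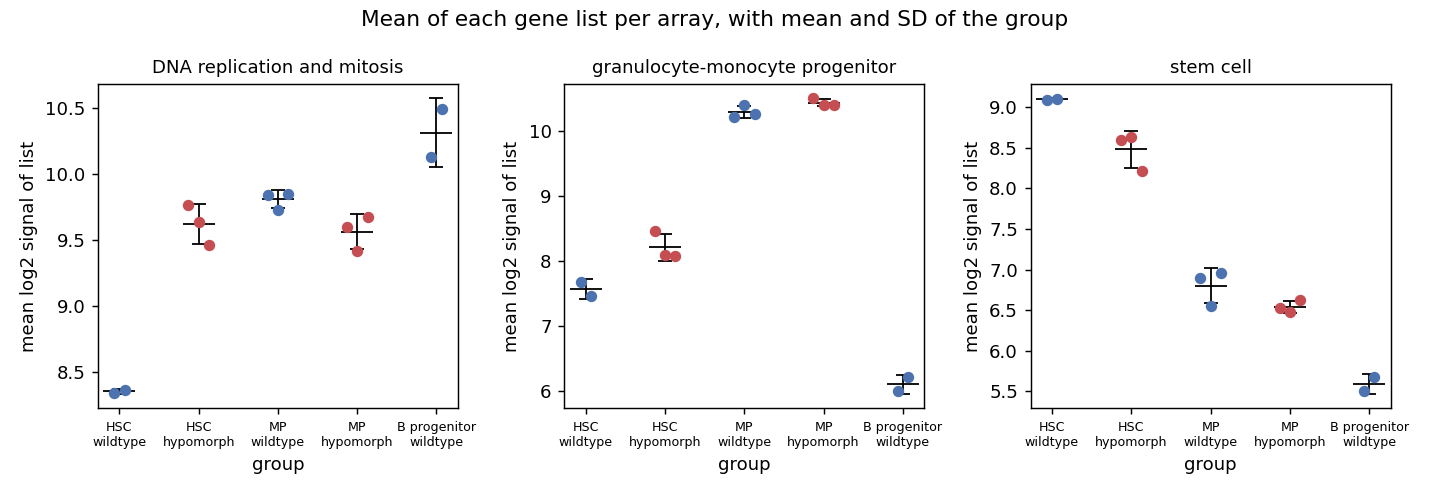
Mean log2 level of the DNA replication and mitosis, granulocyte-monocyte progenitor and stem cell lists on each of the 13 arrays, by group, where each point is an array and the bar is the group mean. The replication list averaged 8.35 in wildtype HSC, 9.62 in hypomorph HSC, 9.81 in wildtype MP and 9.56 in hypomorph MP.

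The other lists were not called by camera in hypomorph MP. The fry test of limma called the B lineage list (median 0.03, mean -0.21, adjusted p = 0.0273) and the imprinted list (median 0.00, mean -0.20, adjusted p = 0.0359) lower, but not with arrays centred (0.777 and 0.745). The 75th percentile filter brought camera calls of the granulocyte-monocyte progenitor (0.0209), mast cell (0.0230) and immediate early (0.0298) lists. None of 34 erythroid genes was called, also adjusted over the list alone (camera adjusted p = 0.361), and the anion exchanger gene Slc4a1 had a value of 2.16 (limma adjusted p = 0.184). In the settings other than leaving out an array, Slc4a1 ran from 0.98 to 2.63. None of 21 megakaryocyte genes was called, with 1 lower adjusted over the list alone (camera adjusted p = 0.965), and Plek had a value of -1.27 (limma adjusted p = 0.142; called without MP wildtype 2, at -1.57 and an adjusted p of 0.0452). In the granulocyte-monocyte progenitor list 1 of 35 rose, the Fc receptor gene Fcgr3 (1.11), with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.104). In the mast cell list 1 of 15 rose, Cma1, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0589). The mast cell list passed the camera threshold on leaving out any of 7 arrays in turn, HSC hypomorph 1 or 2, HSC wildtype 1 or 2, MP hypomorph 1, and MP wildtype 1 or 2 (adjusted p from 0.0261 to 0.0480). In the B lineage list 3 of 35 fell, Dntt, the transcription factor gene Bach2 (-1.55) and Il7r, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.792). In the macrophage and stroma list 1 of 15 rose, also adjusted over the list alone, the adhesion molecule gene Vcam1 (2.16, camera adjusted p = 0.845). In the stem cell list 1 of 45 rose, the cytokine signalling inhibitor gene Socs2 (1.84), and 1 fell, Fgd5 (-1.74), with 3 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.101). The stem cell list passed the camera threshold without a filter (adjusted p = 0.00993), with arrays centred and without MP wildtype 2 (median -0.31, adjusted p = 0.0217). In the p53 list 1 of 25 rose, Perp (2.00), also adjusted over the list alone (camera adjusted p = 0.845). In the DNA methylation machinery 1 of 22 rose, Gadd45b (1.20), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.792). None of 30 imprinted genes was called, with 4 lower adjusted over the list alone (camera adjusted p = 0.465), and Ndn had a value of -0.94 (limma adjusted p = 0.0684; called without HSC hypomorph 3 or MP wildtype 2, with adjusted p from 0.0289 to 0.0498). In the interferon list 1 of 39 fell, Irgm1 (-1.36), also adjusted over the list alone (camera adjusted p = 0.964). In the immediate early and heat shock list 1 of 29 rose, Gadd45b, and 1 fell, Hspa1b, with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.162; adjusted p = 0.0421 without MP wildtype 3). None of the 4 sex-linked genes was called, also adjusted over the list alone (camera adjusted p = 0.925), and Xist had a value of -1.20 (SE 1.61). Arrays of each MP group differed widely in sex-linked genes, so here too a balance of sex is not shown.

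The count of 75 genes in MP became 38 without MP hypomorph 2, 43 without MP wildtype 1, 40 without MP wildtype 3, 135 without HSC hypomorph 3 and 184 without MP wildtype 2, and 164 with only the 6 MP arrays in the fit. The majority turned in the last 2 of these, to 75 higher and 109 lower, and to 80 higher and 84 lower. Of the 23 named genes called in MP, 12 kept their call whichever array was left out, and 11 did not. Those without MP hypomorph 2 were Fcgr3, Padi4, Cma1, Bach2, Flt3, Thy1, Socs2, Fgd5, Gadd45b, Irgm1 and Hspa1b. The adjusted p of these genes in the fits that ended their calls ran from 0.0609 to 0.0856 for Fcgr3, from 0.0598 to 0.141 for Padi4, from 0.0585 to 0.0662 for Cma1, from 0.0553 to 0.209 for Bach2, from 0.0508 to 0.187 for Flt3, and from 0.0874 to 0.178 for Thy1. It ran from 0.0525 to 0.184 for Socs2, from 0.0515 to 0.0710 for Fgd5, from 0.0525 to 0.236 for Gadd45b, from 0.0664 to 0.269 for Irgm1 and from 0.0609 to 0.0940 for Hspa1b. The further arrays whose absence ended calls were MP wildtype 1 (all 11 but Hspa1b), MP wildtype 3 (all 11 but Fgd5), MP hypomorph 1 (Fcgr3, Padi4, Bach2, Flt3, Thy1, Gadd45b and Irgm1), MP hypomorph 3 (Padi4, Flt3, Thy1, Socs2 and Hspa1b), MP wildtype 2 (Flt3 and Socs2), HSC hypomorph 1 (Flt3), HSC hypomorph 2 (Flt3, Socs2, Gadd45b and Irgm1) and either B progenitor array (Bach2, Gadd45b and Irgm1). Averaging probe sets took Socs2 to 0.48 (adjusted p = 0.289) and Bach2 to -0.45 (0.298), ending their limma calls. It moved Vcam1 to 0.92 and Gadd45b to 0.80, and brought calls of Plek (-1.52) and Ndn (-1.80). Calls were also lost in the second normalization (Bach2, Gadd45b and Irgm1), without a filter (Bach2, Flt3, Socs2 and Irgm1) and with arrays centred (Flt3), with limma adjusted p from 0.0533 to 0.0628. Array weights brought calls of Plek, Ndn, Id2, Slc4a1 and Nusap1, and of Cebpa (0.42, adjusted p = 0.0424) with the default estimator alone.

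The overlap of both comparisons was tested for genes that changed in both cell types. The comparisons share no array, but both use the residual variance of each gene from the same fit. The numbers for independent lists below are therefore not exact values for no shared change. Genes higher in both hypomorph populations numbered 21, against 2.31 for independent lists (Fisher's exact test, p = 5.55e-16). They included the meiotic genes Slc25a31, Syce1, Tex12 (2.76 in HSC and 2.48 in MP), Stag3 (1.05 and 1.46) and Rec8 (0.88 and 1.91), together with the cyclin gene Ccnd1 (2.73 and 2.47), Cma1, Cryab and Perp. Genes lower in both numbered 13, against 1.73 for independent lists (Fisher's exact test, p = 4.10e-09), and included Dnmt1, Mmp2, Hmga2 (-1.26 and -3.33) and the receptor gene Met (-1.45 and -1.93). Tex12, Stag3, Rec8, Ccnd1 and Met are named after their values were seen. Another 4 genes were called in opposite directions, BC018473, Gda, Tmem53 and Tpm4, and are also named after their values were seen. Across all 12745 genes, which are not independent replicates, the fold changes had a Pearson r of 0.0173 and a Spearman rho of -0.0566. The 34 shared genes became 21, 12 higher and 9 lower, without MP wildtype 1 and also without MP wildtype 3, and 11 were higher and 12 lower without MP hypomorph 2.

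The difference between the genotype effects in HSC and MP was tested as an interaction. The effect in HSC was the more positive for Ccr1 (5.08), Depdc1a (4.75), Dntt (4.59), the cohesin acetyltransferase gene Esco2 (4.36) and Ccne2 (4.30), and the more negative for BC018473 (-2.99), Pde2a (-2.97), Selenom (-2.89), Meg3 (-2.72) and the keratin gene Krt8 (-2.64), as log2 differences with limma adjusted p from 2.13e-05 (Ccr1) to 0.0161 (Selenom). In the DNA replication and mitosis list 27 of 48 genes had a more positive effect in HSC and 0 a more negative one (40 and 0 adjusted over the list alone), with a median of 1.41 (camera adjusted p = 3.86e-28; adjusted p = 0.0416 with an estimated correlation). Over all genes the interaction was called for 717, 417 more positive and 300 more negative in HSC. That count was 241, 283, 320, 373, 292 and 246 without MP wildtype 1, HSC hypomorph 2, HSC wildtype 2, MP hypomorph 1, MP hypomorph 2 and MP wildtype 3, and 1444, 1114 and 1242 without HSC hypomorph 3, HSC wildtype 1 and MP wildtype 2. The call of Selenom was lost without HSC wildtype 2 or MP wildtype 1 (adjusted p from 0.0505 to 0.0697), and averaged probe sets moved Ccr1 to 2.92, Esco2 to 2.62, BC018473 to -1.65 and Meg3 to -1.25.

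Wildtype MP were compared with wildtype HSC to describe how these sorted populations differ. The plasma transglutaminase gene F13a1 was 7.79 (SE 0.34) higher on the log2 scale in MP, Ctsg 6.56 (SE 0.39), Ms4a3 6.52 (SE 0.42) and Chdh 6.46 (SE 0.25). The immunoglobulin heavy chain gene Igha (-8.16, SE 1.05), the joining chain gene Jchain (-6.51, SE 0.55), Myl10 (-5.58, SE 0.64) and Ltb (-5.48, SE 0.28) were lower in MP, and so was the stem cell list member Tgm2 (-4.88; -3.21 with probe sets averaged). Igha and Jchain mark antibody-secreting cells, and Igha stood at 13.42 ± 0.02 (SD, n = 2) in wildtype HSC, 12.31 ± 0.91 (SD, n = 3) in hypomorph HSC and 5.26 ± 0.08 (SD, n = 3) in wildtype MP. Their difference need not be a change on myeloid commitment, and whether antibody-secreting cells were in the HSC sort was not tested. In all, 4050 genes passed a limma adjusted p of 0.05, 1757 higher and 2293 lower in MP, around a median shift of -0.12, and 2627 of these changed by at least 2-fold. The majority turned with arrays centred, to 2025 higher and 1981 lower, and at the 75th percentile filter, to 1586 higher and 1574 lower. The count was 2548 without HSC wildtype 2. Of 35 granulocyte-monocyte progenitor genes 26 were higher and 0 lower (27 and 1 adjusted over the list alone; camera adjusted p = 3.43e-20; adjusted p = 0.0162 with an estimated correlation). Of 45 stem cell genes 33 were lower and 0 higher (37 and 0 adjusted over the list alone; median -2.23; camera adjusted p = 2.47e-17; adjusted p = 0.0172 with an estimated correlation). Of 48 replication genes 42 were higher and 0 lower (43 and 0 adjusted over the list alone; median 1.42; camera adjusted p = 4.32e-21; adjusted p = 0.0239 with an estimated correlation). In the interferon list 25 of 39 genes were lower and 1 higher (27 and 1 adjusted over the list alone; camera adjusted p = 2.61e-08; adjusted p = 0.0404 with an estimated correlation). Of 34 erythroid genes 12 were higher, led by the aquaporin gene Aqp1 (3.55) and the carbonic anhydrase gene Car1 (3.46), and 6 lower, also adjusted over the list alone (camera adjusted p = 0.0451; adjusted p = 0.325 with an estimated correlation). That call was lost without HSC hypomorph 1, HSC wildtype 2 or MP wildtype 2 (median from -0.11 to 0.06, adjusted p from 0.0541 to 0.168), with arrays centred and at the 75th percentile filter. The fry test of limma called the B lineage list lower in MP (adjusted p = 0.0226), but not with arrays centred (0.8495). In camera the B lineage list was not called (5 higher and 4 lower of 35, 5 and 3 adjusted over the list alone, camera adjusted p = 0.868), with Dntt higher (1.85) and Cd72 lower (-1.86) in MP.

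Among hypomorph cells, 1485 genes differed between MP and HSC, 533 higher and 952 lower in MP, and 972 without HSC hypomorph 2. The granulocyte-monocyte progenitor list was higher in MP, with 26 of 35 genes higher and 0 lower (28 and 1 adjusted over the list alone; camera adjusted p = 3.08e-32; adjusted p = 0.00234 with an estimated correlation). The stem cell list was lower, with 37 of 45 genes lower and 0 higher (39 and 0 adjusted over the list alone; camera adjusted p = 2.21e-31; adjusted p = 0.00234 with an estimated correlation). Of 48 replication genes 0 were higher and 1 lower (0 and 0 adjusted over the list alone; median -0.07; camera adjusted p = 0.987).

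The genotype effect in HSC was set against the wildtype difference of MP from HSC, to ask whether the hypomorph change runs in the direction of myeloid progenitors. Both use the wildtype HSC arrays. The covariance of the log2 differences across 12745 genes was 0.468, against 0.0524 in simulations without any effect that shared those arrays. Their correlation was 0.746. The simulated correlation, 0.600, is no baseline for that value, since the simulations held no difference of MP from HSC and so a smaller spread. With a different wildtype HSC array on each side, the covariance was 0.378, against -2.92e-05 simulated, and the correlation 0.537. Genes are not independent replicates here. Exchanging the arrays does not remove what both wildtype HSC arrays share. No covariance with the difference of B progenitors from HSC was computed, so a direction particular to MP is not shown. With B progenitor arrays, hypomorph HSC arrays correlated at 0.804 to 0.843 and wildtype HSC arrays at 0.758 to 0.796. With wildtype MP arrays these ranges were 0.924 to 0.952 and 0.866 to 0.908.

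Wildtype B progenitors were compared with HSC and with MP. The Fc receptor-like gene Fcrla was 10.11 (SE 0.21) higher on the log2 scale in B progenitors than in HSC, the B cell coactivator gene Pou2af1 9.63 (SE 0.23), the recombinase gene Rag1 9.28 (SE 0.22) and the B cell linker gene Blnk 8.11 (SE 0.25). Lower in B progenitors were Tgm2 (-8.43, SE 0.27), Fkbp9 (-8.42), Tmem40 (-8.23), the transferrin receptor gene Tfr2 (-7.76), Gcnt2 (-7.54), the myeloperoxidase gene Mpo (-7.47), the erythroid and megakaryocyte transcription factor gene Nfe2 (-7.24), Prtn3 (-5.93) and the erythroid gene Hemgn (-3.77). With probe sets averaged Tgm2 was -4.64 and Gcnt2 -1.79. Of 35 B lineage genes 33 were higher and 0 lower, also adjusted over the list alone (median 4.61; camera adjusted p = 4.22e-34; adjusted p = 9.50e-06 with an estimated correlation). In the megakaryocyte list 15 of 21 were lower and 0 higher (17 and 0 adjusted over the list alone; camera adjusted p = 2.55e-05; adjusted p = 0.0105 with an estimated correlation), and in the stem cell list 39 of 45 were lower and 1 higher (40 and 1 adjusted over the list alone; camera adjusted p = 5.87e-14; adjusted p = 0.0217 with an estimated correlation). In limma 5737 genes passed an adjusted p of 0.05, 1888 higher and 3849 lower, around a median shift of -0.25, and with arrays centred 57.4% were higher against 32.9% without.

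In MP against B progenitors the granule genes Mpo (9.84, SE 0.23), Ctsg (9.17, SE 0.39) and Prtn3 (9.16, SE 0.21) were higher, as were Ms4a3 (7.88, SE 0.42), Car1 (6.13), Nfe2 (5.99), the angiopoietin gene Angpt1 (5.82) and Ifitm1 (5.36), with Angpt1 at 2.99 when its probe sets were averaged. Fcrla (-10.12, SE 0.19), Pou2af1 (-9.86), Rag1 (-9.50) and Blnk (-8.79) were lower. Of 35 granulocyte-monocyte progenitor genes 32 were higher and 1 lower (33 and 1 adjusted over the list alone; camera adjusted p = 2.51e-20; adjusted p = 0.00528 with an estimated correlation), and of 35 B lineage genes 33 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 2.94e-39; adjusted p = 5.45e-06 with an estimated correlation). In limma 4571 genes passed an adjusted p of 0.05, 3148 higher and 1423 lower in MP, around a median shift of 0.13, and with arrays centred 39.7% were higher against 68.9% without.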

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

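The genotype effect differed between HSC and MP by a test of the difference itself, and a signal appeared among probe sets without 1 gene symbol; for the explanations weighed here, what would exclude them was set before the results were seen where 1 array or 1 normalization is the cause, for B progenitors and for the splits of arrays, and after the results were seen for all others. The difference of effects was called for 417 genes with a more positive and 300 with a more negative effect in HSC. The largest log2 differences were those of Ccr1 (5.08), Depdc1a (4.75), Dntt (4.59), Esco2 (4.36) and Ccne2 (4.30), and of BC018473 (-2.99), Pde2a (-2.97), Selenom (-2.89), Meg3 (-2.72) and Krt8 (-2.64). Among gene lists, the median differences were 1.41 for DNA replication and mitosis, 0.69 for mast cells, basophils and eosinophils, 0.34 for granulocyte-monocyte progenitors, 0.31 for p53 targets and cell cycle inhibitors, 0.31 for the DNA methylation machinery, -0.39 for imprinted genes, -0.48 for the interferon response and -0.54 for immediate early and heat shock genes. Only the replication list kept its call in camera with an estimated correlation (adjusted p = 0.0416). The 75th percentile filter ended the camera calls of the granulocyte-monocyte progenitor, p53, DNA methylation machinery, imprinted and interferon lists (adjusted p from 0.0637 to 0.0995), and leaving out 1 array those of the p53, DNA methylation machinery and immediate early lists. The median difference of granulocyte-monocyte progenitor genes was 0.17 and 0.16 without HSC hypomorph 1 and 2, that of the mast cell list 0.42 without HSC hypomorph 1 and 1.08 without HSC wildtype 2, and that of p53 targets 0.49 without HSC wildtype 1 and 0.54 without MP wildtype 2. At the 75th percentile filter that of the mast cell list was 1.72 and that of imprinted genes -0.06, in the second normalization that of the mast cell list was 1.05, and with probe sets averaged that of p53 targets was 0.10 and no longer called. Of 3798 tested probe sets without 1 gene symbol, limma called 94 higher and 132 lower in hypomorph HSC, and 7 higher and 1 lower in hypomorph MP.

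The myeloid genes that were higher in hypomorph HSC could come from MP cells in the sort, from a subset of such cells, or from a single array. A share of 0.195 of MP cells of all kinds, the median implied by the called genes, leaves 0.468 of the 47 genes at least 4-fold higher in MP more than 1 log2 below their predicted level, among them Elane at 5.56 against 10.2 predicted. That share rests on the members that rose, and at its lower quartile, 0.0847, 11 of the 47 genes still lie as far below, so MP cells of all kinds are excluded as the whole cause. A subset of MP cells cannot be told apart, since the implied share differs by a factor of 3.81 between quartiles and no profile of a subset is in the data. The set test kept a p of at most 2.52e-07 without any 1 array and in the other normalization, which excludes a single array as the cause.

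The replication and mitosis genes that were higher in hypomorph HSC could come from MP cells in the sort, from scaling, or from a single array. The share of MP cells implied by 30 members at least 2-fold higher in MP was 3.95 times that implied by 286 other genes at least 4-fold higher in MP (1.05 against 0.267). This excludes MP cells of all kinds as the whole cause, and a part of the rise from such cells is not excluded. The test was not repeated with the same fold for both sets of genes. With arrays centred the median rise was 1.28 against 1.21 without. The median over all genes was shifted by only -0.11 in HSC, so centring could not have taken the rise away. The test thus shows only that the medians of the deposited arrays do not give the rise, and cannot decide on scaling before that. Without any 1 array the adjusted p of camera was at most 8.02e-21, which excludes a single array. More dividing cells in the sort and higher expression in each cell give the same values and were not separated.

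The lymphoid genes that were lower in hypomorph MP could come from B progenitors in the wildtype MP sort or from fewer lymphoid-primed cells in the hypomorph sort. The share of B progenitors implied by Dntt, 0.1402, predicts a median difference of -2.28 for 99 genes highest in B progenitors. The measured median was -0.00324. This excludes cells with the mean profile of the sorted B progenitors as the source of the fall of Dntt. A subset of B progenitors low in those genes was not tested, since no profile of a subset is in the data. The lymphoid priming list had a median of -0.52, but with an estimated correlation the adjusted p of camera was 0.158, so fewer lymphoid-primed cells can be neither excluded nor accepted.

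The groups of the 6 MP arrays and of the 6 hypomorph arrays can each be split in 10 ways, which are too few for a share under 0.05. The real split called 75 genes in MP and 1485 between MP and HSC, 1 of 10 in both, and the highest other split called 0 in both.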

How the results depend on the processing

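Each result was counted once per alternative setting, so the same list or gene can be counted many times. In this way 312 counts stayed within 1.5 times their value and 50 moved. Another 85 main values kept their direction and call, or for the covariance stayed within 1 SD between wildtype HSC arrays (0.0241), and 4 covariances did not. Direction and side of the threshold were kept in 2573 list results and 2614 gene results. A call was lost in 100 list results and 114 gene results, and gained in 61 and 22. Dnmt1 stayed called in both cell types without any 1 array, from -2.94 to -2.53 in HSC and from -3.43 to -3.22 in MP, and the myeloid list kept its direction (0.14 to 0.39 without 1 array, 0.06 to 0.41 in the other settings, the lowest with 200 genes). Leaving out 1 array gave 453 to 1796 genes in HSC, 38 to 184 in MP, 241 to 1444 for the difference of effects, 2548 to 4549 for MP against HSC in wildtype, 972 to 2017 in hypomorph, 21 to 41 shared genes, 3 to 7 lists in MP, 5 to 9 lists for the difference, and a covariance of 0.361 to 0.404, for which leaving out a wildtype HSC array gives no value; a lone HSC wildtype array is assumed to vary like the other groups. Array weights, whose default estimator did not converge, gave 2346 genes in HSC, 3932 for the difference, 6050 for MP against HSC in hypomorph and 251 shared genes. In MP they gave 4615, 1839 higher and 2776 lower. Weights gene by gene, chosen after seeing the data, gave 3903 in MP, 1468 higher and 2435 lower. They gave 2717 for the difference, 3264 for MP against HSC in hypomorph and 113 shared genes. With weights, other splits of the 6 MP arrays called up to 4675 (default) and 3402 (gene by gene) genes, so these counts do not separate genotype from array structure. The estimated correlation left 2 lists in HSC, 1 in MP, 1 for the difference, 3 for MP against HSC in hypomorph, 5 for B progenitors against HSC and 6 for MP against B progenitors. It lay above the preset 0.01 for some lists (0.204 for neutrophil genes) and below it for others (-0.014 for imprinted genes). Every probe set, which tests more features, gave 2081 in HSC, 6546 for MP against HSC in wildtype, 10253 for B progenitors against HSC and 8369 for MP against B progenitors. The filter at the 75th percentile gave 8 lists in MP, 4 for the difference and a covariance of 0.462 (setting chosen after seeing the data), no filter a covariance of 0.270, and the mean of probe sets 0.293; the cause was not tested. A fold change of at least 2 left 2627 genes for MP against HSC in wildtype, by construction. Only the arrays compared, with fewer arrays for the spread, gave 139 in HSC and 164 in MP, so the order of these counts turned. In that setting each comparison used its own spread instead of the spread shared by the 5 groups. Arrays of a group correlated at 0.949 to 0.981 in HSC hypomorph and 0.961 in HSC wildtype. The correlations were 0.983 to 0.988 in MP hypomorph and 0.978 to 0.995 in MP wildtype. The fry test called 13 lists for MP against HSC in hypomorph, and gave a direction opposite to that of camera for DNA methylation machinery in MP against B progenitors (median 0.13, adjusted p = 0.00903) and T and NK cell genes in B progenitors against HSC (median -0.00083, adjusted p = 0.0144). With arrays centred, chosen after seeing the data, fry had the direction of camera, which called neither, for both (medians -0.28 and 0.47, adjusted p = 0.0275 and 0.605), so the opposite directions came with the shift over all genes; it called 3 lists in MP. The replicate number as a block gave 896 genes in HSC, 59 in MP and 375 for the difference, and ended the limma calls of Cd79b and Tbxas1 in HSC and of Bach2, Flt3, Gadd45b, Irgm1, Padi4, Socs2 and Thy1 in MP (adjusted p from 0.0603 to 0.0997); arrays of the same number are not stated to be paired, not every array correlated best with its own number, and the correlations of deviations ran from -0.199 to 0.301. Signal over background was not measured, so it is not known which dim genes lie at background.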

Other observations

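The test of germline genes in the next sentence was chosen after the results were seen. Germline and pluripotency genes were over-represented among the genes higher in both hypomorph cell types, with 4 of 21 from the list of 24 against 0.0395 for independent lists (Fisher's exact test, p = 5.67e-08). The list was written with 68 genes, of which these 24 were tested. Germline genes low in wildtype cells could enter the test through hypomorph arrays alone, so the 24 may favour this result.

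Some genes varied widely within groups. Eif2s3y, on the Y chromosome, ran from 2.75 to 9.35 among the MP wildtype arrays, from 2.35 to 8.68 in HSC wildtype, from 2.87 to 9.22 in MP hypomorph, from 2.47 to 10.16 in B progenitors and from 6.95 to 9.31 in HSC hypomorph. Xist, expressed from the inactive X chromosome, ran from 8.13 to 12.44 in MP hypomorph and from 4.61 to 12.86 in B progenitors. Arrays within groups other than HSC hypomorph therefore differed in their mix of male and female cells. The HSC hypomorph arrays also differed in Eif2s3y, over a narrower range, so their mix may differ too. Sex was not a term in any fit. The mean of the 4 sex-linked genes was 7.86 on HSC wildtype 1 and 5.25 on HSC wildtype 2. On the HSC hypomorph arrays this mean ran from 6.82 to 7.69, so in HSC sex was not separated from genotype. Igha stood at 7.37 and 12.74 on the B progenitor arrays. Hspa1b ran from 10.21 to 12.12 in MP wildtype and from 5.11 to 8.96 in MP hypomorph.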
